A study of Mus musculus with 4 samples.

How the data were processed

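Visium libraries, in which barcoded spots beneath a tissue section capture polyadenylated RNA, were available for 4 sections of mouse heart after ligation of the left anterior descending coronary artery. The labels give a horizontal and a vertical section (replicates 1 and 2) of each of 2 models, named MI and MI-E, from fresh-frozen tissue of 10 µm thickness permeabilised for 18 minutes. The deposited matrices hold raw UMI counts (a UMI marks 1 captured molecule) for 32285 genes in the spots under tissue, made by the authors with Space Ranger 1.2.1 on the mm10 build according to the submitters' processing notes. No normalisation had been applied to the deposited counts, and a spot mixes RNA from several cells. Spot positions were not used, so nothing here describes where in a section a spot lay.

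Counts were summed over all spots of a section, and the sums were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, its default filter on low counts, and model and plane as terms. This leaves 1 residual degree of freedom, moderated across genes. The SE given with a gene's fold is the fold divided by the square root of the test's F statistic. It therefore rests largely on the spread pooled over genes, and not on that gene's sections alone. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say whether the sections of a model come from 1 heart, so p-values measure the spread between sections, which may be technical, and not the spread between animals. Per-plane differences are log2 ratios of TMM-normalised CPM, 1 section against 1, with no test. Interaction of model and plane could not be tested, since it would leave no residual degree of freedom.

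Of 47 gene lists of cell type markers and programmes, 46 had at least 4 genes past the filter and were tested with camera of limma 3.58.1, at the preset correlation between genes of 0.01 and again with an estimated correlation. Lists that carry a cell type's name were read as lists of genes and not as counts of cells. The text names genes by a rule. For the model comparison it takes the 12 with the largest fold in each direction among genes past the threshold with a mean of at least 20 CPM and the same sign in both planes, filled up, where fewer passed, by genes ranked on the smaller of the per-plane folds and said not to pass. For the plane, region and spot-range comparisons it takes 6 in each direction. Symbols made of Gm and digits or ending in Rik are passed over. In addition it takes 16 genes always named in the model and plane comparisons and up to 4 members of each described list, those with the smallest p. The lists, tests, thresholds, naming rule and alternative settings were chosen before the data were examined, except where stated.

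Spots of all sections were clustered together by the Leiden method (leidenalg 0.10.2, scikit-learn 1.9.0) on 2000 variable genes centred within each section, 30 principal components and 15 neighbours at resolution 0.5. A region could be compared if it held at least 50 spots in every section, and the ECM-rich region was the qualifying one with the highest median UMI share of the fibrillar extracellular matrix list. A planned myocardial region could not be formed, because only the ECM-rich region qualified. In its place, and after the clusters had been seen, spots were divided by the share of their UMIs from 15 ventricular cardiomyocyte genes into a cardiomyocyte-rich range (at least 3%) and a cardiomyocyte-poor range (under 1%), with those 15 genes left out of the test. Co-variation of lists across spots is the Spearman correlation of their UMI shares within a section, after every spot had been thinned to 3391 UMIs and spots below that had been left out.

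Shares of spots carry exact Clopper-Pearson 95% intervals, which cover counting error only. A gene was treated as having a shared 3′ end when at least 50% of the 31-base words in the last 300 bases of its transcripts also occur in another gene of the annotation. Of the genes in the matrices, 32158 were matched to the annotation. The fit was tested on simulated data with the depths of these sections, a dispersion of 0.05 and 200 changed genes. For whole sections it recovered 20% of genes changed 2-fold and 86% of genes changed 4-fold, with 3 false calls.

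Alternatives tried were DESeq2 1.42.0 and its size factors, library totals without TMM, no filter, no plane term, other clustering and spot-range settings, thinning to the lowest section total, spots with at least 1000 UMIs, removal of mitochondrially encoded, haemoglobin and ribosomal protein genes, and leaving out each section. Fits without a section dropped the term that was not tested, so there model and plane are partly confounded, and the lone section of a group was assumed to vary like the others. With 2 sections per model, an exact permutation test cannot give a p below 0.333.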

Results

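The data are 4 Visium sections of the hearts of C57BL/6J mice aged 8-9 weeks, operated to close the left anterior descending coronary artery. A horizontal and a vertical section stood for each of the models MI and MI-E. The labels state neither what the E stands for nor how long after surgery the hearts were taken. The sections held 1589 (MI horizontal), 1674 (MI vertical), 1771 (MI-E horizontal) and 2056 (MI-E vertical) spots. Their total UMI counts, in the same order, were 45092562, 19804808, 47594696 and 24476686, and the median UMIs per spot were 24831, 6861.5, 28076 and 10795.5. Xist, which is transcribed from the inactive X chromosome, had 1, 0, 0 and 0 counts, and the Y-linked gene Ddx3y had 1301, 973, 1541 and 1029.

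Sections of the same model differed in composition. Ventricular cardiomyocyte genes, which encode the contractile apparatus and the energy supply of working heart muscle, took a median of 1.5% of a spot's UMIs in the MI horizontal section and 3.86% in the MI vertical section. In MI-E these medians were 1.41% and 5.31%. Pan-macrophage genes took 0.607% and 0.880% in the horizontal sections of MI and MI-E, against 0.191% and 0.127% in the vertical ones. Fibrillar extracellular matrix genes took 1.93%, 1.04%, 2.21% and 0.541% in the MI horizontal, MI vertical, MI-E horizontal and MI-E vertical sections. Mitochondrially encoded transcripts made up 15.9%, 28.7%, 12.1% and 40.1% of all UMIs in that order. Cardiomyocyte-rich spots made up 28.9% (exact 95% interval 26.7-31.2) of the MI horizontal section and 58.0% (55.6-60.4) of the MI vertical section. They made up 15.2% (13.5-16.9) of the MI-E horizontal section and 69.5% (67.4-71.4) of the MI-E vertical section.

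**Figure D1:**
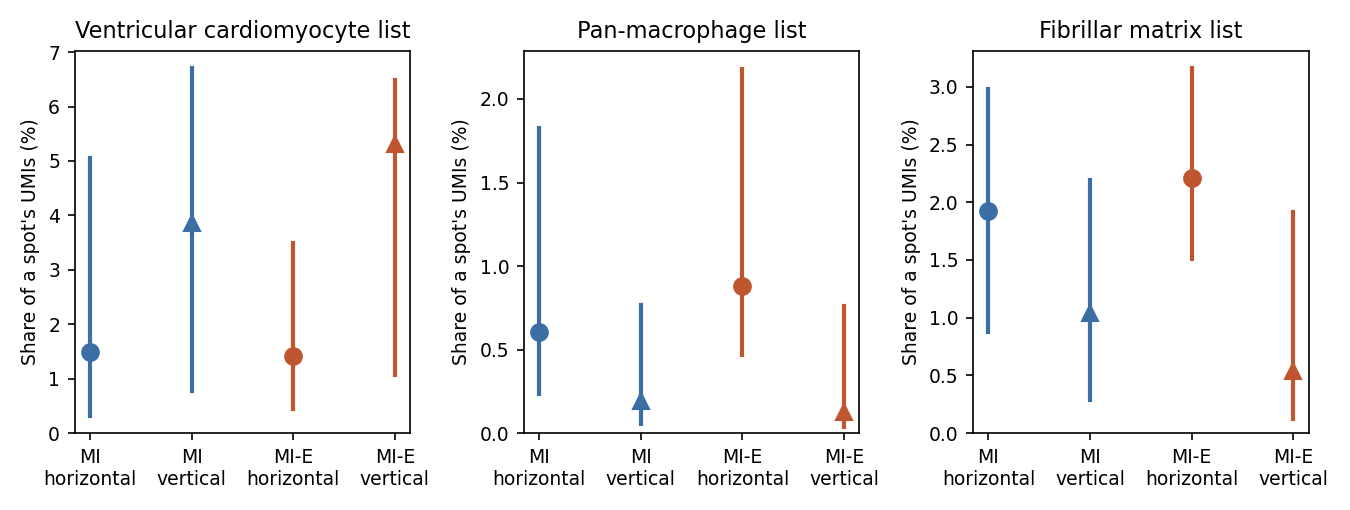
Percentage of a spot's UMIs taken by each of the plotted gene lists, by section, with points for the median and bars from the 10th to the 90th percentile over spots. The ventricular cardiomyocyte medians are 1.5% and 1.41% in the horizontal sections and 3.86% and 5.31% in the vertical sections of MI and MI-E.

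The first comparison, MI-E against MI over whole sections, addresses which genes differ between the models in a series on macrophages that settle in the infarcted heart. Hp, C4b, C3 and Fbln1 were among the genes higher in MI-E in both planes, and Thbs4, Myh7 and Igfbp3 among those lower. C4b, Fbln1 and C3 were also among the leading genes of a cluster of spots (region 11, with Comp and Pi16) that held 5.54% of the MI-E vertical and 2.21% of the MI vertical section, and 0.508% and 0.252% of the horizontal sections. Hp (ENSMUSG00000031722, mm10 chromosome 8, 109575128-109579172), the haptoglobin gene, whose product binds free haemoglobin, was higher by log2 1.03 ± 0.15 (SE, 2 sections per model), with 43.8 and 16.6 CPM in the MI horizontal and vertical sections and 87.2 and 34.9 in MI-E. C4b and C3, central components of the complement cascade, were higher by 0.96 ± 0.21 and 0.93 ± 0.27, and Fbln1, a matrix glycoprotein, by 0.93 ± 0.24. These differences were larger in the vertical plane, with C4b at 0.58 in horizontal and 1.37 in vertical sections, C3 at 0.41 and 1.46 and Fbln1 at 0.445 and 1.42. C3 and Hp were at least 2-fold lower in the MI vertical section than in every other section. Thbs4 (ENSMUSG00000021702, chromosome 13, 92751590-92794818), a matricellular protein, was lower in MI-E by log2 -1.20 ± 0.18, with 57.7 and 66.0 CPM in MI against 30.2 and 23.6. Myh7, the slow myosin heavy chain that stressed mouse ventricle re-expresses, was lower by -0.93 ± 0.17, and Igfbp3 by -0.77 ± 0.20. Myh7 was at least 2-fold higher in the MI vertical section than in every other section. Igfbp3 was at least 2-fold lower in the MI-E horizontal section than in every other section.

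None of these genes passed the test. edgeR called 0 of 14906 genes higher and 0 lower in MI-E after Benjamini-Hochberg adjustment (lowest adjusted p = 0.999), with 323 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each direction. The other genes highest in MI-E by the naming rule had log2 folds from 0.44 (Akap8l) to 0.69 (Kcnk3), with Islr at 0.60, Cbr2 at 0.57, Gpc1 at 0.46, and Bloc1s1 at 0.64, Cfb at 0.58 and Ly6c2 at 0.49, whose 3′ ends are shared with other genes and whose levels are therefore uncertain. The other lowest genes lay between -0.46 (Adamts1) and -0.60 (Ccr1, a chemokine receptor of myeloid cells), and included Socs3 at -0.54, Phlda1 at -0.56, Trp53i11 at -0.57, Bambi at -0.55, Apobec1 at -0.52, Nipsnap3b at -0.51 and Sdf2l1 at -0.54. Among macrophage genes, Folr2 stood at 0.42, Timd4 at 0.47, Lyve1 at -0.08, Ccr2 at -0.15, Trem2 at -0.10, Gpnmb at -0.12, Spp1 at -0.39, Cd68 at -0.25 and C1qa at 0.15 (-0.0016 with library totals). Postn stood at -0.32, Col1a1 at -0.09, Nppa at -0.52, Nppb at -0.39 and Hbb-bs, which has a shared 3′ end, at -0.56. The planes went apart for several of these genes, as for Lyve1 (-0.79 in horizontal and 0.55 in vertical sections), Timd4 (-0.50 and 1.37) and Hbb-bs (-1.28 and 0.16). Across the 5612 genes with at least 20 CPM, 44.1% had the same sign in both planes, and the Spearman correlation of the planes' folds was -0.21, across genes, which are not independent replicates. Without the MI-E horizontal section 14 genes were called higher, and without the MI-E vertical section 4 were called higher and 1 lower.

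Among the fixed gene lists, camera called 12 higher and 11 lower in MI-E of 46 tested (Benjamini-Hochberg), while 0 were called in either direction with an estimated correlation, where each of the 23 had adjusted p = 0.682 and 0 lists had an unadjusted p under 0.05. Without the MI horizontal section camera called 6 higher. No member of any list passed edgeR's test over all genes, so counts below are of members with 1 sign in both planes, followed by those passing when adjusted over the list alone. Activated fibroblast genes, which mark the matrix-producing state of healing scar, had a median log2 of -0.36, with 8 of 14 lower in both planes and 1 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.74e-09, and adjusted p = 0.682 with an estimated correlation). Its members with the smallest p were Thbs4, Cilp (-0.56), Cthrc1 (-0.46) and Meox1 (-0.38). With library totals the activated fibroblast medians were -0.07 in horizontal and -1.01 in vertical sections. Among spots of equal cardiomyocyte share they averaged -0.10 and -0.41 over 6 bins (SD 0.20 and 0.53, library totals). Inflammatory cytokine genes had a median of -0.26, with 12 of 15 lower in both planes and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.15e-08, and adjusted p = 0.682 with an estimated correlation), with Ccl4 at -0.55, Il6 at -0.79 and Osm at -1.07. Among spots of equal cardiomyocyte share their median went both ways, from -0.35 to 0.65 over 6 bins in the horizontal plane and from -1.15 to 0.51 in the vertical plane (library totals). Immediate early genes, the first transcribed after a stimulus, had a median of -0.37, with 10 of 15 lower in both planes and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.89e-07, and adjusted p = 0.682 with an estimated correlation), with Nr4a1 at -0.56 and Egr1 at -0.51. Border zone cardiomyocyte genes had a median of -0.35, with 6 of 14 lower in both planes and 1 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.30e-06, and adjusted p = 0.682 with an estimated correlation). Myh7 and Acta1 (-0.58) led them, and their medians were 0.03 in horizontal and -0.62 in vertical sections.

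Complement genes were higher in 8 of 11 members in both planes, with a median of 0.29 and 3 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.02e-05, and adjusted p = 0.682 with an estimated correlation), led by C4b, Cfb, C3 and C1s1 (0.40). Resident macrophage genes had a median of 0.28, with 6 of 12 higher in both planes and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00277, and adjusted p = 0.682 with an estimated correlation). Cbr2, Folr2, Vsig4 (0.68) and the haemoglobin scavenger receptor gene Cd163 (0.36) had the smallest p in that list. Pan-macrophage genes were not called, with a median of 0.02 (-0.14 with library totals), a mean of -0.05 and a test direction of lower (camera, Benjamini-Hochberg adjusted p = 0.196, and adjusted p = 0.761 with an estimated correlation). T and NK cell genes were higher in both planes in 9 of 12 members, with a median of 0.67 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.30e-06, and adjusted p = 0.682 with an estimated correlation). Cd8a stood at 1.44, Cd3d at 1.01 and Nkg7 at 0.77. With library totals the T and NK cell medians were 0.78 in horizontal and -0.04 in vertical sections. The list took a median of only 0.004% of a spot's UMIs in the MI-E horizontal section and 0% in each of the others.

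Fatty acid oxidation genes had a median of 0.29, but -0.50 in horizontal and 1.02 in vertical sections, with 1 of 18 higher in both planes and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00215, and adjusted p = 0.682 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes (-0.34 and 0.77) and TCA cycle genes (-0.31 and 0.72) had the same 2 signs, as did ventricular cardiomyocyte genes (-0.67 and 1.01) and mitochondrially encoded genes (-0.54 and 0.86), and the share of cardiomyocyte-rich spots was lower in MI-E in the horizontal plane and higher in the vertical plane. Ventricular cardiomyocyte genes (median 0.19) and mitochondrially encoded genes (0.14, and -0.01 with library totals) were not called. Library totals in place of TMM shifted the median of all genes by -0.15. The remaining called lists were higher for atrial cardiomyocyte, mesothelial, B and plasma cell, mast cell, calcium handling and adipocyte genes, and lower for erythroid, interferon response, fibrillar extracellular matrix, proliferation, angiogenesis, TGF-beta response and heat shock genes, with medians from -0.55 (erythroid) to 1.61 (mast cell). These directions are of the fit over both planes and do not say that the planes agree. The erythroid gene Hbb-bs, for example, stood at -1.28 in horizontal and 0.16 in vertical sections. Mast cell genes took a median of 0% of a spot's UMIs in every section. Fibrillar extracellular matrix genes had a median of -0.11, at 0.08 in horizontal and -0.41 in vertical sections, with 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00331, and adjusted p = 0.682 with an estimated correlation).

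The vertical sections were then set against the horizontal ones, with model as a term, because the labels name a plane for every section. Heart muscle genes were higher and most pan-macrophage and interferon response genes lower in the vertical plane. Yipf7 was higher by log2 3.14 ± 0.51 (SE, 2 sections per plane) and Hopx, a homeodomain-only cofactor, by 3.01. Hrc, which binds calcium in the sarcoplasmic reticulum, was higher by 2.81 and Pdk4, which restrains glucose oxidation, by 2.74. Rpl3l and Lrtm1 stood at 2.83 and 2.76. In MI the rise of these genes ran from log2 1.42 (Pdk4) to 2.13 (Hopx), 1 section against 1. In MI-E it ran from 3.88 (Hopx) to 4.39 (Yipf7), and it was larger there for each gene. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546-49070929), a glycoprotein of lipid-laden macrophages, was lower by -2.81 ± 0.21, with 264 and 268 CPM in the horizontal and 41.4 and 34.5 in the vertical sections of MI and MI-E. Ccl8 (-2.16), Ccl5 (-1.97) and Irf7 (-2.01), a master regulator of interferon genes, were lower too, as were Ly6c2 (-2.54) and Ftl1 (-2.10), which have shared 3′ ends and uncertain levels.

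edgeR called 1771 genes higher and 1470 lower in vertical sections of 14906 tested (Benjamini-Hochberg), and 83.0% of genes with at least 20 CPM had the same sign in both models. With library totals, which shifted the median of all genes by -0.48, the split was 325 higher and 1518 lower, and DESeq2 called 1139 higher and 744 lower. The counts fell strongly without the MI-E horizontal section, and also without the MI horizontal section. They did not fall in this way without either vertical section. Fits without a horizontal section had no model term and took their spread from the vertical sections alone. Those differed more between the models than the horizontal ones did (median absolute log2 0.18 against 0.13). The fall therefore does not show that the counts rest on a single section.

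Macrophage genes did not move as a block. Cd68 fell by 1.60, C1qa by 1.47 and Trem2, a lipid receptor, by 1.75 on the log2 scale in vertical sections. Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607-110863239), a hyaluronan receptor of vessel-associated resident macrophages and lymphatic endothelium, rose by 2.63 ± 0.32 (edgeR, Benjamini-Hochberg adjusted p = 0.00367), from 2.96 to 11.6 CPM in MI and from 1.71 to 17.0 in MI-E. Timd4, a phosphatidylserine receptor of resident macrophages, rose by 1.96 ± 0.59 (edgeR, Benjamini-Hochberg adjusted p = 0.0487) at low levels, from 0.370 to 0.724 in MI and from 0.258 to 1.89 in MI-E. Cd163 rose by 1.48 (edgeR, Benjamini-Hochberg adjusted p = 0.00626), while Folr2 fell by 0.75 and Igf1 by 0.92. Ccr2, which marks monocyte-derived cells, fell by 0.58. Of 12 resident macrophage genes, 4 rose and 3 fell, and the same numbers passed adjusted over the list alone. Lymphatic genes, a list that also holds Lyve1, rose in 3 of 6 members, with Prox1 at 1.69 and Mmrn1 at 1.79, and in 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00915, and adjusted p = 0.528 with an estimated correlation). The resident macrophage list was not called and its median of 0.17 became -0.30 with library totals (camera, Benjamini-Hochberg adjusted p = 0.446, and adjusted p = 0.642 with an estimated correlation).

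**Figure D2:**
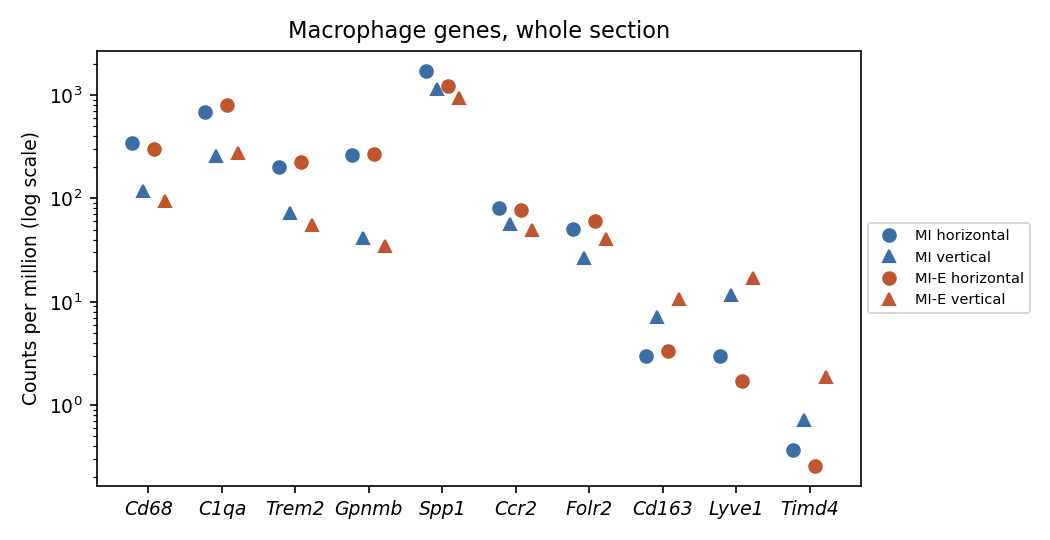
CPM (log scale) of macrophage genes in each of the 4 sections, with 1 point per section. Gpnmb lies at 264 and 268 in the horizontal sections and 41.4 and 34.5 in the vertical ones, and Lyve1 at 2.96 and 1.71 against 11.6 and 17.0.

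Of 14 pan-macrophage genes, 13 fell in vertical sections, and 13 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.56e-10, and adjusted p = 0.528 with an estimated correlation), with a median log2 of -1.50 and Aif1 at -1.87. The share of cardiomyocyte-rich spots was higher in the vertical section of both models. Of 14 lipid-associated macrophage genes, 6 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000176, and adjusted p = 0.528 with an estimated correlation), with Fabp5 at -1.77 and Lgals3 at -1.61. Interferon response genes fell in 12 of 15 members, and in 14 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.89e-09, and adjusted p = 0.528 with an estimated correlation), with Zbp1 at -1.75 and Ifit3 at -1.27. T and NK cell genes fell in 11 of 12 members, and in 11 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.14e-07, and adjusted p = 0.528 with an estimated correlation), with Cd3d at -2.56 and Nkg7 at -2.31. Activated fibroblast genes fell in 5 of 14 members, and in 7 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000606, and adjusted p = 0.528 with an estimated correlation), with Runx1 at -0.81. Col1a1 (-0.84) and Postn (-0.76) did not pass.

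Fatty acid oxidation genes rose in 16 of 18 members, and in 17 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.89e-09, and adjusted p = 0.528 with an estimated correlation), with Acsl1 at 2.30 and Cpt1b at 1.64. Calcium handling and ion channel genes rose in 15 of 16 members, and in 16 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.90e-09, and adjusted p = 0.528 with an estimated correlation), with Ryr2 at 1.95 and Hcn4 at 3.02. Ventricular cardiomyocyte genes rose in 11 of 15 members, and in 15 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.49e-07, and adjusted p = 0.528 with an estimated correlation), with Ckm at 2.26 and Ttn at 1.77. Angiogenesis genes rose in 6 of 14 members and fell in 1, and 9 rose and 1 fell adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000362, and adjusted p = 0.528 with an estimated correlation), with Nrp1 at 2.28 and Vegfa at 1.59. Myh7 rose by 1.12 and Nppb, the B-type natriuretic peptide gene, by 1.54, while Nppa (0.06, and -0.41 with library totals), Spp1 (-0.48) and Hbb-bs (0.69) did not pass. camera called 16 lists higher and 12 lower of 46 (Benjamini-Hochberg), and 0 with an estimated correlation, where the lowest adjusted p = 0.528.

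**Figure D3:**
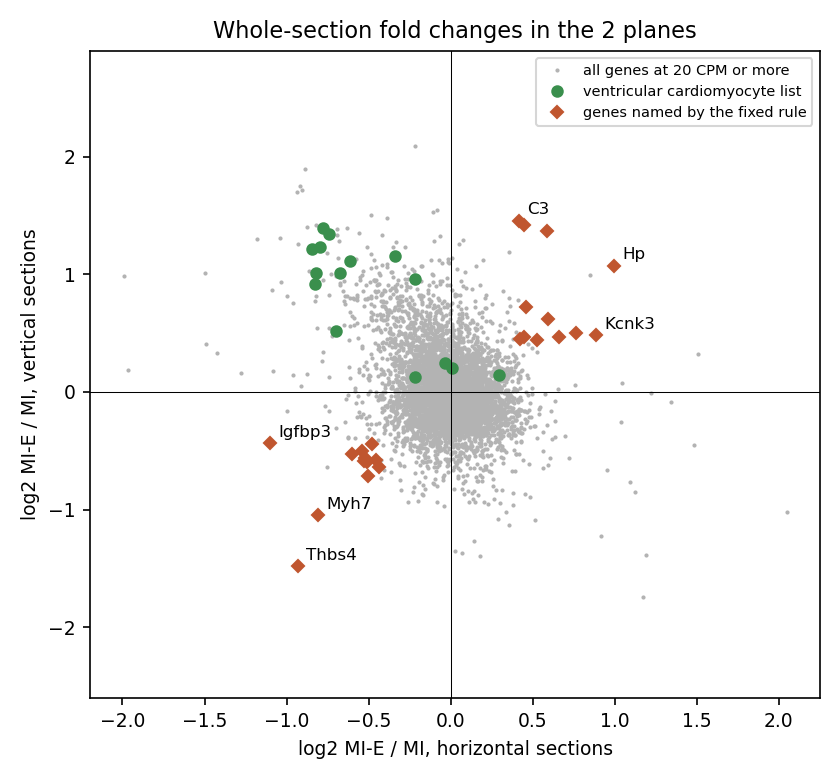
Log2 MI-E against MI of each gene with at least 20 CPM, in the horizontal sections (x) and the vertical sections (y), with members of marked lists coloured. Of the 5612 genes, 44.1% have the same sign on both axes, and Myl7 (-1.99 and 8.68) lies outside the frame.

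Clustering of all 7090 spots gave 13 regions, most of them held largely by 1 plane. Region 2, led by Myh7, Myh6 and Nppa, held 28.4% and 32.0% of spots in the horizontal sections of MI and MI-E and 0.538% and 0.0486% in the vertical ones. Region 3 (Nppa, Acta1, Nppb) held 22.6% and 18.1% of the vertical sections and 2.83% and 1.36% of the horizontal ones. Region 4 (Gpnmb, Ms4a4c, Irf7, Fabp5) held 20.6% and 20.8% of the horizontal and 0.896% and 0.243% of the vertical sections, whereas region 6 (Spp1, Gpnmb, Lgals3, Arg1) held 13.9% and 12.8% of the vertical sections and 0 and 0.169% of the horizontal ones. The count of 0 among 1589 spots leaves room for up to 0.232% (upper exact 95% bound). Region 8 (Hrc, Tcap, Ckm) held 24.7% of the MI vertical section and 0.195% of the MI-E vertical section, and region 7 (Efnb3, Ces1d) held 0.836% and 21.4%.

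Region 1, led by Arg1, Igfbp3, Cxcl5, S100a9 and S100a8, was the only one with at least 50 spots in every section. It took the place of the ECM-rich region because no other region qualified. Of the fibrillar matrix list only Timp1 was among its leading genes. Its spots were shallow, with median UMIs of 11126.5, 2770, 18886 and 2427 in the MI horizontal, MI vertical, MI-E horizontal and MI-E vertical sections, below the median of all spots of each section, and Gm42418 and Lars2, chosen after their values were seen, were among its leading genes. It held 30.6% (exact 95% interval 28.3-32.9) and 15.2% (13.5-17.0) of the MI horizontal and vertical sections and 33.7% (31.5-36.0) and 11.3% (9.99-12.8) of the MI-E sections. The models' mean shares were 22.9% ± 10.9 and 22.5% ± 15.8 (SD over the sections of a model). The difference of -0.388 percentage points was smaller than the pooled SD of 13.6, but that SD holds the spread between planes. Within planes, the MI-E share was higher in the horizontal sections (33.7% against 30.6%) and lower in the vertical ones (11.3% against 15.2%). With a section left out the planes were unequal. The difference was then 7.29 without the MI horizontal, -8.06 without the MI vertical, -11.6 without the MI-E horizontal and 10.8 without the MI-E vertical section.

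MI-E was then compared with MI within the spots of region 1. Igkc (ENSMUSG00000076609, chromosome 6, 70726435-70726966), the immunoglobulin kappa constant gene, rose in MI-E by log2 1.78 ± 0.26, at 1.79 in the horizontal and 1.73 in the vertical plane (edgeR, Benjamini-Hochberg adjusted p = 2.88e-08). The vertical value rests on 12 UMIs in MI and 21 in MI-E, and over whole vertical sections Igkc was lower in MI-E, at 7.10 against 11.99 CPM. Slpi, a secreted protease inhibitor, rose by 0.99, S100a9, an alarmin of neutrophils and monocytes, by 0.75, and Hp by 0.92. H2-T23 rose by 1.05 and Myh6 by 0.75. Bambi, a decoy receptor of TGF-beta signalling, fell by 1.02, Cxcr6, a chemokine receptor of T cells, by 0.96, and Sprr1a by 0.74. AY036118 fell by 1.03, but its 3′ end is wholly shared with other genes. Spry1 (-0.75) and Cxcl10 (-0.64) did not pass.

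edgeR called 20 genes higher and 8 lower in region 1 of 12294 tested (Benjamini-Hochberg), with 471 at an unadjusted p under 0.05. Here edgeR pooled the spread over genes entirely, so that a gene whose planes went apart was judged by the shared spread. Of the 28, 20 had the same sign in both planes, 6 had a shared 3′ end, and 12 differed at least 2-fold in the horizontal plane alone. Bc1, chosen after its values were seen, was called higher at 3.69 with 124 CPM in the MI-E horizontal section and 4.21, 14.5 and 8.28 in the MI horizontal, MI vertical and MI-E vertical sections. DESeq2, chosen after seeing the data, called 0 in each direction, as did edgeR without the plane term, and library totals left 2 higher and 0 lower. The counts were 6 higher and 2 lower without the MI horizontal section, 5 and 0 without the MI vertical section, 14 and 1 without the MI-E horizontal section, and 1 and 0 without the MI-E vertical section, and Hp stood at -0.0505 and AY036118 at 0.11 without the MI-E horizontal section.

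In region 1 immediate early genes were lower in both planes in 12 of 15 members, 0 passed over all genes and 2 were lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.02e-07, and adjusted p = 0.785 with an estimated correlation), with Egr1 at -0.75 and Dusp1 at -0.61. Of 9 neutrophil genes, S100a9 rose and 3 were higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.78e-06, and adjusted p = 0.785 with an estimated correlation). Erythroid genes had a median of -0.62, with Hbb-bt called lower at -0.69 and 6 of 7 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.68e-10, and adjusted p = 0.785 with an estimated correlation). Medians in the horizontal and vertical planes were -1.11 and 0.08 for erythroid genes and 0.61 and -0.15 for neutrophil genes. Complement genes were higher in both planes in 7 of 10 members, 0 passed over all genes and 2 were higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0105, and adjusted p = 0.785 with an estimated correlation). Pan-macrophage genes had a median of 0.17, with 8 of 14 higher in both planes and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0272, and adjusted p = 0.785 with an estimated correlation).

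In cardiomyocyte-rich spots, a range added after the clusters had been seen, most complement and antigen presentation genes were higher in MI-E in both planes. C3 stood at log2 1.25 (0.92 in horizontal and 1.58 in vertical sections), C4b at 0.87, Ccl8 at 0.82, Fbln1 at 0.92, Pltp at 0.70 and the class II gene H2-Ab1 at 0.63. Thbs4 stood at -1.37 (-0.72 and -2.03), Acta1, the skeletal alpha-actin gene, at -0.99, Ifit1 at -0.94, Igfbp3 at -0.76, Ccl12 at -0.59 and a copy of Ccl21a with a shared 3′ end at -0.67. Complement genes had a median of 0.42, with 9 of 11 higher in both planes and 3 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.62e-09, and adjusted p = 0.880 with an estimated correlation). The antigen presentation list had 7 of 8 members higher in both planes, with a median of 0.61 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.09e-07, and adjusted p = 0.880 with an estimated correlation). Activated fibroblast genes had 9 of 14 members lower in both planes, a median of -0.53 (-0.14 in horizontal and -1.10 in vertical sections) and 1 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.25e-16, and adjusted p = 0.880 with an estimated correlation). Lists of other immune cells were called higher too, namely resident macrophage (median 0.17), monocyte (0.34), neutrophil (0.30), T and NK cell (0.57) and B and plasma cell genes (0.64), with camera Benjamini-Hochberg adjusted p from 0.00656 to 0.00966, and adjusted p = 0.880 with an estimated correlation for each. Atrial cardiomyocyte (median 0.65, at 0.05 in horizontal and 1.44 in vertical sections) and mesothelial genes (1.06) were called higher as well (camera, Benjamini-Hochberg adjusted p = 1.83e-06 for each, and adjusted p = 0.880 with an estimated correlation). Monocyte, neutrophil and T and NK cell medians were 0.68, 1.08 and 0.95 in the horizontal plane but -0.57, -0.45 and 0.03 in the vertical plane. In the horizontal plane the cardiomyocyte-rich spots of MI-E lay nearer the 3% bound, with a median cardiomyocyte share of 3.77% against 4.47% in MI. Pan-macrophage genes were not called, with medians of 0.42 and -0.02 in these planes (camera, Benjamini-Hochberg adjusted p = 0.0574, and adjusted p = 0.916 with an estimated correlation). No single gene passed, as edgeR called 0 of 13013 in each direction (Benjamini-Hochberg, lowest adjusted p = 0.128), with 187 at an unadjusted p under 0.05, while DESeq2 called 1 higher and 0 lower. The calls were 97 higher and 27 lower without the MI-E horizontal section and 19 and 10 without the MI-E vertical section, and the planes' folds had a Spearman correlation of -0.49 across genes, which are not independent replicates.

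In cardiomyocyte-poor spots, Igkc stood at log2 1.16 in MI-E against MI, H2-T23 at 1.32, Slpi at 0.87, the stromal gene Cd248 at 0.70, Cbr2 at 0.70 and the iron exporter gene Slc40a1 at 0.62. Ralgds stood at -0.71, Fam43a at -0.69, Kcne4 at -0.63, Usp25 at -0.60 and Smoc2 at -0.56. Immediate early genes had a median of -0.38 (-0.53 in horizontal and 0.04 in vertical sections), with 7 of 15 lower in both planes and 4 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.99e-07, and adjusted p = 0.843 with an estimated correlation). Inflammatory cytokine genes had a median of -0.23 (-0.49 in horizontal and 0.12 in vertical sections), with 6 of 15 lower in both planes and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000647, and adjusted p = 0.843 with an estimated correlation). Complement genes were higher in both planes in 8 of 11 members, with a median of 0.17 and 1 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00661, and adjusted p = 0.843 with an estimated correlation). Resident macrophage genes had a median of 0.22, with 4 of 11 higher in both planes and 1 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0106, and adjusted p = 0.843 with an estimated correlation). edgeR called 0 of 13278 genes in each direction (Benjamini-Hochberg, lowest adjusted p = 0.228), with 509 at an unadjusted p under 0.05, while DESeq2 called 1 higher and 0 lower and library totals gave 32 higher and 21 lower. The calls were 1 higher without the MI vertical section, 2 higher without the MI-E horizontal section, and 4 higher and 1 lower without the MI-E vertical section.

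Across spots, pan-macrophage and fibrillar extracellular matrix genes varied together in every section. Their Spearman correlation was 0.517 in MI horizontal, 0.720 in MI vertical, 0.321 in MI-E horizontal and 0.680 in MI-E vertical, with a mean of 0.559 ± 0.181 (SD, n = 4 sections). Both fell with the ventricular cardiomyocyte share, pan-macrophage shares at -0.746 ± 0.060 and fibrillar matrix shares at -0.670 ± 0.182. Their correlation was not adjusted for that share, so it does not show a link particular to macrophages and matrix. Fibrillar matrix shares also went with monocyte shares at 0.667 ± 0.142. Pan-macrophage shares went with lipid-associated macrophage shares at 0.781 ± 0.113 and with resident macrophage shares at 0.605 ± 0.027. Activated fibroblast and pan-macrophage shares had correlations of 0.599 and 0.596 in the vertical sections and 0.238 and 0.0007 in the horizontal ones. Border zone and pan-macrophage shares had -0.557 and -0.679 in the horizontal sections of MI and MI-E and -0.207 and 0.0961 in the vertical ones. The depth cut left out 383 spots of the MI vertical and 310 of the MI-E vertical section. It left out only 8 and 7 of the horizontal sections, so the planes are not compared on like spots. No p is given, since spots are not replicates and 105 pairs of 15 lists were correlated in 4 sections.

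**Figure D4:**
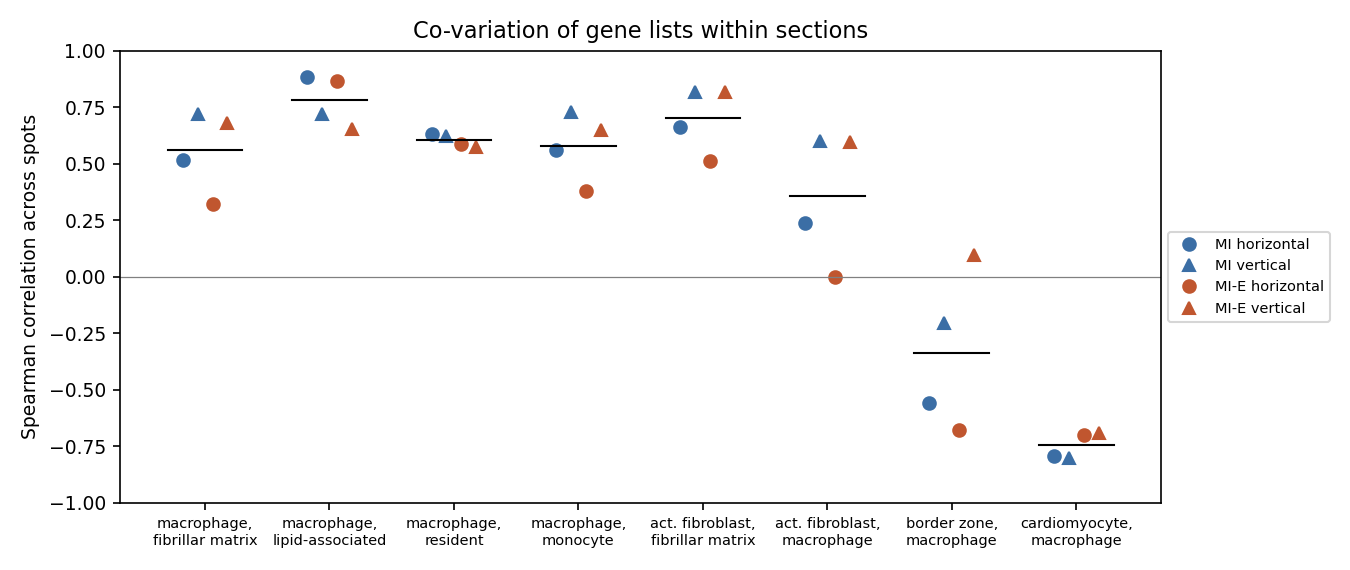
Spearman correlation across spots of pairs of gene list shares, with 1 point per section and a line at the mean. Pan-macrophage and fibrillar extracellular matrix shares lie between 0.321 and 0.720 in the 4 sections.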

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

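The tests of shared 3′ ends were chosen after the result had been seen, and the narrower version of that test after the outcome of the first version, while the bins of equal cardiomyocyte share were chosen after the composition of the sections had been seen but before any value within them. Ventricular cardiomyocyte genes were lower in MI-E than in MI in the horizontal sections (median log2 -0.67) and higher in the vertical sections (1.01). Mitochondrially encoded genes had medians of -0.54 and 0.86 in the same planes. The share of cardiomyocyte-rich spots differed between MI-E and MI by -13.8 percentage points in the horizontal sections and by 11.5 in the vertical sections. In each case the planes moved in opposite directions, and that difference between planes was not tested, since each model has 1 section per plane.

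Fatty acid oxidation and mitochondrially encoded genes had opposite signs in the planes. Removal of mitochondrially encoded, haemoglobin and ribosomal protein genes before scaling left the vertical minus horizontal difference of the fatty acid oxidation median at log2 1.51, against 1.52 with them (SE 0.217), but TMM already trims such genes and the median of all genes did not move either, so this decides nothing about mitochondrial RNA having set the scale, and with library totals the medians were -0.40 and 0.61 in the planes, against -0.50 and 1.02. Different shares of cardiomyocyte-rich spots stay open, since within bins of equal cardiomyocyte share the difference was 0.299 against 0.948 over whole sections (both with library totals, SD over 6 bins 0.380), and for mitochondrially encoded genes 0.344 against 0.890 (SD 0.116). These lie below 0.5 of the whole-section value by less than 1 SD, so that different sampling of the heart and other causes cannot be told apart by them. The fatty acid oxidation difference rose from bin to bin, from -0.176 at a share of 0 to 1% to 0.831 at 5 to 6%. Its SD therefore holds a trend and not only scatter. The bin of 5 to 6% held only 26 spots of the MI-E horizontal section. A difference between the models that depends on the plane stays open as well and was not tested.

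Pan-macrophage genes were lower in vertical sections, while Lyve1, Timd4 and Cd163 were higher. These 3 are resident macrophage genes that rose, while others of that list, such as Folr2, fell. Timd4 had only 19, 14, 15 and 34 UMIs in the MI horizontal, MI vertical, MI-E horizontal and MI-E vertical sections, and Lyve1 99 in MI-E horizontal. Their values within bins therefore lean on the 0.5 count added to each. With all sections thinned to the lowest total the pan-macrophage median was log2 -1.51, against -1.50 (SE 0.0851), but thinning leaves the ratios of abundant genes where they were, so this decides nothing about the shallower sequencing of the vertical sections. Within bins of equal cardiomyocyte share the pan-macrophage median was -0.973 against -1.95 over whole sections (SD 0.257), and the mean of Lyve1, Timd4 and Cd163 was 1.19 against 1.54 (SD 0.653), both within 1 SD of the 0.5 of the whole-section value that was set as the bound. A smaller share of cardiomyocyte-poor spots in the vertical sections and other causes therefore cannot be told apart by this bound for either set of genes. Pan-macrophage genes were lower in every bin, however, from -0.98 to -0.78 in MI and from -1.85 to -0.53 in MI-E. These values argue against that share as the whole cause of the pan-macrophage fall, as far as the bins equalise it. A difference between the planes in which macrophages each section holds stays open too, and Lyve1 is also expressed by lymphatic vessels, whose genes Prox1 and Mmrn1 were higher in vertical sections as well.

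In the MI-E horizontal section 28 genes lay at least 2-fold above or below all the other sections, among them S100a8, S100a9, Igkc, H2-T23 and Bc1 (higher) and Hbb-bs, Hba-a1, Alas2, Igfbp3 and AY036118 (lower). Of the 28, 17.9% (5 genes, exact 95% interval 6.06-36.9) had a shared 3′ end, against 2.19% of 10253 genes at the same level, which goes with reads of near-identical genes having been assigned differently in that section as a candidate explanation for part of the set. With mitochondrially encoded, haemoglobin and ribosomal protein genes left out, the share was 8.70% of 23 genes (1.07-28.0) against 1.82%, an interval that holds the bound of 1.5 times the background, so for these genes the explanation cannot be told apart from others and the outcome of the first version rests on the genes left out. Alas2, which shares no 3′ end, was lower together with the haemoglobin genes, and 23 of the 28 had no shared end by this measure. A difference that belongs to the model or to that heart stays open and was not tested, since it is a single section.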

How the results depend on the processing

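Alternatives chosen after seeing the data were those for the spot ranges, and DESeq2 and its size factors for region 1. The myocardial region could not be formed at any setting, so none of its alternatives was run, and resolution 1.0, no centring and spots with at least 1000 UMIs gave no qualifying ECM-rich region. On simulated data the fit recovered 20% of genes changed 2-fold for whole sections, 17% for region 1 and 25% for cardiomyocyte-rich spots. At the simulated dispersion of 0.05 most changes of that size were therefore missed in each, at the depth of whole sections as well. The square root of the dispersion fitted to the data was 0.178 for whole sections, 0.129 for region 1 and 0.206 for cardiomyocyte-rich spots. Each is below that of the simulation, so the rates do not carry over directly. In region 1 genes changed less than 2-fold were called, such as S100a9 and Myh6 (0.75 each). Where no alternative is named, counts stayed within 1.5 times their reported value. The cause was not tested for any change below, except that fits without a section compare models across unequal planes.

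For whole sections, the call of 0 genes in each direction (edgeR, 323 at an unadjusted p under 0.05) became 2 higher with library totals and 28 higher and 10 lower with no filter, and ran from 0 to 14 higher and 0 to 1 lower without a section. In the plane comparison library totals gave 325 higher and DESeq2 1139 higher and 744 lower, and without a section the counts ran from 0 to 2831 higher and 0 to 2255 lower. Called lists (12 higher, 11 lower) became 0 and 0 with an estimated correlation and ran from 6 to 15 higher and 9 to 14 lower without a section. In region 1 the counts (20 and 8) became 0 and 0 with no plane term and with DESeq2, 2 and 0 with library totals, and 30 and 16 at resolution 0.3, and ran from 1 to 14 and from 0 to 2 without a section. In cardiomyocyte-rich spots (edgeR 0 and 0, 187 at an unadjusted p under 0.05) they became 1 higher with library totals and with DESeq2 and 8 higher and 1 lower with no filter, and ran from 0 to 97 and from 0 to 27. In cardiomyocyte-poor spots (edgeR 0 and 0, 509 at an unadjusted p under 0.05) they became 32 and 21 with library totals, 48 and 37 with no filter, 1 higher with DESeq2 and 2 higher at 1.5%, and ran from 0 to 4 and from 0 to 1. The difference in the share of region 1 was 1.39 at resolution 0.3 and ran from -11.6 to 10.8 without a section. The correlation of pan-macrophage and matrix shares was 0.606 without thinning, 0.552 as Pearson correlation and 0.506 to 0.639 without a section.

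Of the 38 genes named for whole sections, 4 turned sign with all sections in the fit and 16 without a section. With library totals C1qa stood at -0.0016, and with no plane term Lyve1 stood at 0.35, Col1a1 at 0.0327 and Trem2 at 0.0454. Without a section the log2 fold ran from -0.48 to 1.72 for Cfb, -0.0582 to 0.99 for Gpc1, -1.30 to 2.25 for Ly6c2, -1.83 to 0.14 for Igfbp3, -0.80 to 0.10 for Postn, -0.79 to 1.05 for C1qa, -1.35 to 0.74 for Nppb, -2.15 to 1.87 for Gpnmb, -0.0072 to 0.92 for Folr2, -1.26 to 0.14 for Hbb-bs, -2.07 to 1.65 for Lyve1, -0.50 to 0.15 for Ccr2, -0.99 to 1.85 for Timd4, -1.28 to 0.75 for Cd68, -0.74 to 0.54 for Col1a1 and -1.30 to 0.97 for Trem2. In the plane comparison Nppa stood at -0.41 with library totals and ran from -0.37 to 0.50 without a section, and each of the 21 called among the 26 named genes lost its call in at least 1 fit without a section. In region 1 Hp ran from -0.0505 to 1.38 and AY036118 from -1.69 to 0.11, and each of the 10 called among the 12 named genes lost its call under some alternative with all sections. In cardiomyocyte-rich spots H2-Ab1 ran from -0.19 to 1.47, the Ccl21a copy (Ccl21a|ENSMUSG00000094686) from -2.68 to 1.31 and Ccl12 from -1.30 to 0.14, and in cardiomyocyte-poor spots Slc40a1 ran from -0.0453 to 1.49.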

Other observations

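The bins of equal cardiomyocyte share and the search for genes that stood apart were chosen after the data had been seen. Complement genes were higher in MI-E at equal cardiomyocyte share. Within bins of equal share the list's median log2 for MI-E against MI was 0.41 in the horizontal and 0.55 in the vertical plane (SD over 6 bins 0.228 and 0.197), and over whole sections, also with library totals, 0.19 and 0.28. T and NK cell genes stood at 1.02 and 0.47 within the same bins (SD 0.464 and 0.601), against 0.78 and -0.04 over whole sections. That list took a median of at most 0.004% of a spot's UMIs in any section. Its values within bins may therefore follow the 0.5 count added to each gene and the unequal totals of the bins. Pan-macrophage genes stood at 0.33 and 0.16 (SD 0.236 and 0.240) against 0.14 and -0.52, and lipid-associated macrophage genes at 0.10 and 0.04 (SD 0.123 and 0.145) against -0.12 and -0.57. Inflammatory cytokine genes, lower in MI-E over whole sections (-0.33 and -0.67), went both ways within the bins, from -0.35 to 0.65 and from -1.15 to 0.51, and immediate early genes stood at -0.06 and -0.19 (SD 0.341 and 0.285) against -0.21 and -0.63. No test was made on these values.

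The MI-E vertical section held 145 genes at least 2-fold above or below all the other sections, 134 of them higher. Atrial genes stood out, with Myl7, the atrial myosin light chain, at 90.6 CPM against 1.21, 0.207 and 0.293 in the MI horizontal, MI vertical and MI-E horizontal sections, and Sln, which regulates the calcium pump of the atrium, at 41.7 against 0.720, 0 and 0. Myl4 had 65.8 against at most 4.08, and Ces1d, a carboxylesterase, 56.1 against at most 4.91. Sprr1a, a stress-induced gene, was lower there, at 259 against 623 to 781, as was the smooth muscle gene Cnn1, at 8.99 against at least 23.6. Region 11, led by Comp and Pi16 and with C4b, Fbln1 and C3 among its leading genes, held 5.54% of that section, 2.21% of the MI vertical section, and 0.252% and 0.508% of the horizontal sections. Of the 2 sections behind its leading genes, Myl7 and Sln led it in 1 only, as their lowest log2 ratios to other spots were -0.03 and 0. Mast cell genes had the highest median of any list for MI-E against MI over whole sections, with Cma1 at log2 1.77, Mcpt4 at 1.74 and Tpsb2 at 1.47 but Kit at -0.47, and 3 higher and 1 lower of the 4 passed adjusted over the list alone while 0 passed edgeR's test over all genes. The list lay near the floor, at a median of 0% of a spot's UMIs in every section. Its 90th percentile over spots was 0.004% and 0.0034% in MI horizontal and vertical, and 0.0033% and 0% in MI-E.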
